A study of Drosophila melanogaster with 6 samples.

How the data were processed

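The series measured the binding of the histone variant H2Av by ChIP-seq in Oregon-R embryos of 14 to 16 h, fixed with 1.8% formaldehyde per the labels' protocols, with 3 ChIP and 3 input libraries. Groups and replicate numbers were taken from the labels. The input numbers do not match the ChIP numbers: per the labels, input 3 served ChIP 1, input 1 served ChIP 2 and input 2 served ChIP 3, so a shared number pairs nothing. The experiment numbers in the labels place ChIP 1 beside its own input and ChIPs 2 and 3 apart from theirs. With 1 list on the one side, a difference between replicate 1 and the others cannot be separated from such a batch.

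The authors aligned reads with Bowtie 0.12.7, per the submitters' processing notes, and deposited regions of significant enrichment on FlyBase release 5, per the file headers, for each ChIP library and for the replicate set. The region caller, its thresholds, the handling of duplicate reads and how the replicates were combined are not given in the sources used here. Each region has a deposited score, which was read as a log2 ratio: the deposited values of each list are, to a relative tolerance of 1e-12, log2 of 1 constant per list times a ratio of whole numbers, for 100% of regions. In simulated data, 100% of 3000 such ratios were recovered, and 0% of 3000 scores that were no such ratio passed. The procedure accepts no score of a list unless many of its scores pass. The 0% therefore concerns a list as a whole and gives no rate at which single scores pass by accident. This reading rests on the values, since no header names the unit. The constant differs between lists and how the authors set it is not given, so scores were used only to rank, filter and describe regions within a list. The numbers of reads behind a ratio were not inferred, and depth is unknown. The precision of a single region's score is therefore unknown as well.

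Sequence lengths came from the file headers, and 0, 1, 2 and 2 regions that ran past the end of a sequence in replicates 1, 2 and 3 and the combined list were ended there. Overlap required at least 1 shared base. Base overlap of pairs of lists was given as a Jaccard index and set against 1000 circular shifts of one list within each sequence. The share of each sequence inside regions was set against the mean of the shares of 2L, 2R, 3L and 3R as a log2 ratio per replicate, with the mean and SD over 3 replicates and an exact two-sided sign-flip permutation test. Shares of regions in the combined list have 95% exact Clopper-Pearson intervals, which cover counting error only. Ranks of scores in pairs of replicates were compared by Spearman correlation over regions that overlapped, each taken with its largest overlap. The interval functions were tested on simulated data (0 mismatches with a count base by base in 50 pairs of lists), and 5.5% of 200 unrelated simulated pairs passed a permutation p of 0.05. Those simulated regions were of equal width and placed at random on a single sequence. They lacked the clustering of the deposited lists, so the shifts were not tested on clustered regions. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

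The comparisons of region numbers, replicate overlap, combined support, X and chromosome 4 against autosomal arms and score ranks, their alternatives and the rule for named regions were chosen before the data were examined. Named regions were the 10 combined regions with the highest score and the 5 widest. Added after the lists were seen were heterochromatic sequence, 2R, windows of 500 kb, stretches without regions, the 5 regions high in every replicate, the centromere-side 2 Mb of each arm, windows of the length of chromosome 4, the share of X among the strongest regions, regions of at least 20 kb and an alternative without regions whose score another region of the list also has. Alternatives were the highest-scoring 50% of each list, the 5 large arms only, lists cut to equal numbers of regions, overlap of at least 50% of both regions, regions under 200.0 bp apart joined, random placement in place of shifts, regions per Mb, bases in all 3 replicates, ranks of width and leaving out each replicate. The gene table at hand is on release 6 and gives no positions that can be set against release 5, so 4 planned results on transcript starts and gene lists were not run, and no gene is named.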

Results

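Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to locate H2Av in the genome of Drosophila melanogaster embryos. H2Av is the histone H2A variant of the fly and takes the roles that H2A.Z and H2A.X share out in other animals, in transcription and in the response to DNA breaks. The embryos were of the wild-type strain Oregon-R and were 14 to 16 h old. The series has 3 ChIP libraries and 3 input libraries, which are chromatin sequenced without the antibody. Each ChIP library has a deposited list of regions enriched over an input, and 1 further list was made for the replicate set as a whole (the combined list). The inputs have no list of their own and enter only as the background of the ChIP lists. Read numbers are not given in the lists, so the depth of each library is unknown. Nothing in the labels says whether the replicates came from separate collections of embryos. SDs over replicates therefore measure the spread between these samples, which may be technical. Sign-flip p-values rest on the signs and sizes of the same 3 values and do not measure that spread. SDs over pairs are of pairs that share a list and are not independent. The p-values from shifts or random placements concern the position of regions along the sequences and do not measure the spread between samples. Positions are on FlyBase release 5. No gene annotation of that release was used here, so regions are named by position alone.

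The first question was how much of the genome H2Av occupied and in what form. The deposited H2Av regions were broad and lay across the genome. The replicate lists held 4403, 5016 and 4763 regions (mean 4727 ± 308, SD, n = 3), and the combined list held 5905. Regions of the replicates had a median width of 3663, 3572 and 3676 bp and together covered 23.4 ± 1.90 Mb (SD, n = 3). The shortest region of each replicate was 1301 bp wide and the widest was 36576, 46912 and 37388 bp. The shortest width was the same in all 3 replicates and was 1001 bp in the combined list, which may be a setting of the unknown caller. Widths and gaps therefore describe the called regions and not H2Av alone. Neighbouring regions on a sequence lay a median 4726 ± 229 bp apart (SD, n = 3). Wider regions had higher scores. The score is the authors' own value for a region, and its Spearman correlation with width across the regions of a list was 0.753, 0.750 and 0.761 in the 3 replicates and 0.710 in the combined list, where regions are not independent replicates.

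Along the chromosome arms H2Av was spread unevenly, and the replicates traced the same profile. In windows of 500 kb, the share of bases inside regions ran from 0 to 48.9% (mean of 3 replicates), with a median of 17.1% over 238 windows of 2L, 2R, 3L, 3R, X and 4. The window with the highest share was 2L from 10.0 to 10.5 Mb with 48.9% ± 1.99 (SD, n = 3), followed by 2R from 19.5 to 20.0 Mb with 48.7% ± 1.89 and 2R from 0.5 to 1.0 Mb with 48.3% ± 5.99. On X the share peaked from 15.5 to 16.0 Mb, at 42.6% ± 3.11 (SD, n = 3). Low windows included 3L from 10.0 to 10.5 Mb, with 1.32% ± 0.309, and 2R from 15.5 to 16.0 Mb, with 1.41% ± 0.296 (SD, n = 3). Across the windows the Spearman correlation between pairs of replicates was 0.988 to 0.994. These windows were chosen after the lists were seen.

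**Figure D1:**
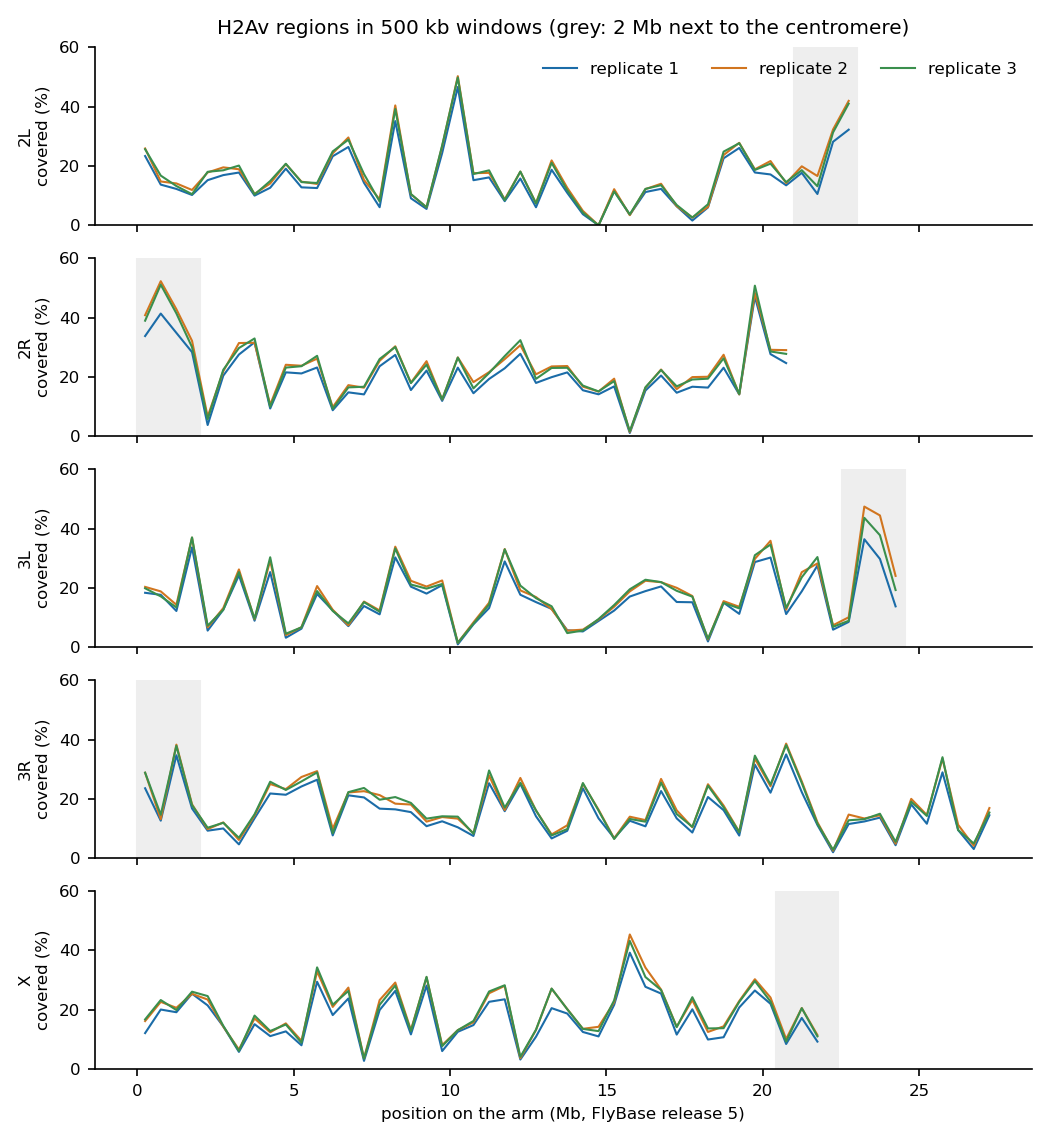
Share of bases inside H2Av regions (%, vertical axis) in full windows of 500 kb along each chromosome arm (Mb, horizontal axis), 1 line per replicate, with the 2 Mb next to the centromere in grey. The 3 lines rise and fall together, from 0 on 2L at 14.5 to 15.0 Mb to 48.9% (mean of 3 replicates) on 2L at 10.0 to 10.5 Mb.

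Long stretches of the arms had no H2Av region in any of the 3 replicates. The longest was on 2L, from 14365975 to 15003418 (637 kb), and the combined list covered 168 of its bases. The next were 563 kb on 2R, from 15562453 to 16125945, then 455 kb on 2L, from 16927780 to 17383218, and 450 kb on 2L, from 15773762 to 16223596. The combined list covered 2678, 238 and 2201 of their bases. A stretch of 418 kb on 3L, from 22283661 to 22701467, had no base in the combined list either. On the 5 large arms, 20 stretches were at least 300 kb long, against at most 1 in any of 1000 random placements of the same regions (one-sided permutation p = 0.001, the smallest that 1000 placements can give). The longest random stretch was 364 kb. How much of each stretch reads could be aligned to was not analysed here.

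**Figure D2:**
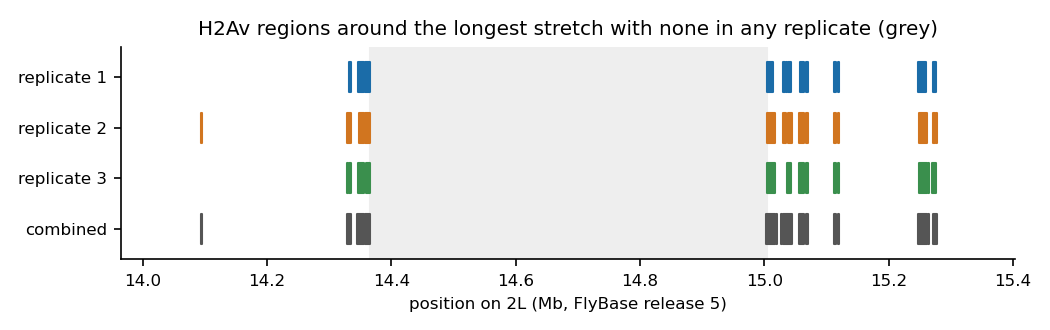
Map of 2L around the longest stretch without a region in any replicate (grey, 14365975 to 15003418), with position in Mb on the horizontal axis and 1 row of boxes per list, each box 1 region. All 3 replicates and the combined list have regions on both sides of the 637 kb.

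The second question was whether chromosomes differed in their share of H2Av. Chromosome 4, the small and largely heterochromatic dot chromosome, had the highest share of all sequences, with 32.2%, 41.0% and 38.7% of its bases inside regions (mean 37.3% ± 4.53, SD, n = 3). The autosomal arms 2L, 2R, 3L and 3R together had 18.1% ± 1.25, and chromosome 4 stood 2.03-fold above the mean of their 4 shares (log2 ratio 1.02 ± 0.081, above 0 in 3 of 3 replicates). It carried 70.3 ± 5.78 regions per Mb against 35.6 ± 1.55 on the autosomal arms (SD, n = 3). The median score of its regions was lower than that of autosomal regions of the same list, by a log2 difference of -0.25 ± 0.062 (SD, n = 3). With the highest-scoring 50% of each list the log2 ratio for chromosome 4 was 0.58 ± 0.35, with 0.24, 0.94 and 0.57 in the 3 replicates. The exact two-sided sign-flip permutation test gave p = 0.25 for the log2 ratios of covered share of chromosome 4, X, 2R and heterochromatic and unplaced sequence as deposited, the smallest value this test allows with 3 replicates, so the test makes no call and the ratios are to be read against their SDs.

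X had the same share of bases inside regions as the mean of the 4 autosomal arms, to within a few hundredths of a log2 unit. Regions held 18.4% ± 1.35 of X and 18.1% ± 1.25 of the autosomal arms (SD, n = 3), and the log2 ratio of X to the mean of the 4 arms' shares was 0.01 ± 0.0086. The sign of so small a ratio depended on the setting, and it was -0.01 when bases in all 3 replicates were counted. Among the autosomal arms, 2R had the highest share, 22.3% ± 1.50, and 2L, 3L and 3R had 16.5% ± 1.10, 17.3% ± 1.28 and 17.0% ± 1.17 (SD, n = 3). In every replicate X lay below 2R and above each of 2L, 3L and 3R. Its shares were 16.9%, 19.3% and 19.1%, against 20.6%, 23.4% and 23.1% on 2R and 15.9%, 18.3% and 17.8% on 3L. X thus matched the mean of the 4 arms and none of them singly. 2R stood 1.32-fold above the mean of the other autosomal arms, with a log2 ratio of 0.40 ± 0.0037 (SD, n = 3), far above the spread between replicates.

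Heterochromatic and unplaced scaffolds as a whole had a smaller share of bases inside H2Av regions than the autosomal arms, with wide differences among the scaffolds. Those that the release assigns to pericentric heterochromatin, the Y or no chromosome (2LHet, 2RHet, 3LHet, 3RHet, XHet, YHet and U) had 6.29% ± 1.71 of their bases inside regions, a log2 ratio of -1.58 ± 0.321 to the mean share of the autosomal arms (SD, n = 3), below 0 in 3 of 3 replicates. The share ran from 18.0% ± 2.08 on XHet, 16.1% ± 2.02 on 2LHet and 14.2% ± 3.28 on 3LHet to 6.00% ± 2.11 on 3RHet, 4.90% ± 1.46 on YHet and 2.65% ± 1.06 on U (SD, n = 3), with 9.80% ± 2.18 on 2RHet. XHet lay slightly above the autosomal arms in replicates 2 and 3 (19.1% against 19.0% and 19.4% against 18.7%), and in the combined list XHet, 3LHet and 2LHet, with 32.9%, 25.3% and 24.9%, all lay above the 22.3% of the autosomal arms. The gap was smaller without U, where the remaining scaffolds had 10.2% ± 2.42, a log2 ratio of -0.87 ± 0.26, or 0.549-fold in place of 0.335-fold. The log2 ratio of regions per Mb was -0.89 ± 0.40 with U and -0.28 ± 0.29 without it, where the replicates had -0.61, -0.06 and -0.18, so without U no lower number of regions stood out from the spread. That of covered share with the highest-scoring 50% of each list was -2.34 ± 0.30 (SD, n = 3). Regions of all these scaffolds together were narrower than on the autosomal arms, with a median of 2135 ± 20.5 bp against 3763 ± 77.8 bp, and scored lower, by a log2 difference of -0.26 ± 0.033 in the median (SD, n = 3), although the median on YHet, with 5 to 8 regions a replicate, was higher by 0.37 ± 0.14 and that on XHet, with 6 to 11, differed by 0.02 ± 0.14. The scaffold Uextra had 0 regions in every list. The comparison is of scaffolds with whole arms, and the arms include their 2 Mb next to the centromere. Those ends had 25.3%, 39.0%, 28.2% and 23.8% of bases inside regions on 2L, 2R, 3L and 3R, and 10.7% on X (means of 3 replicates). How much of these scaffolds reads could be aligned to was not analysed here, so a low share may not mean little H2Av. Comparisons with heterochromatic sequence were added after the lists were seen.

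**Figure D3:**
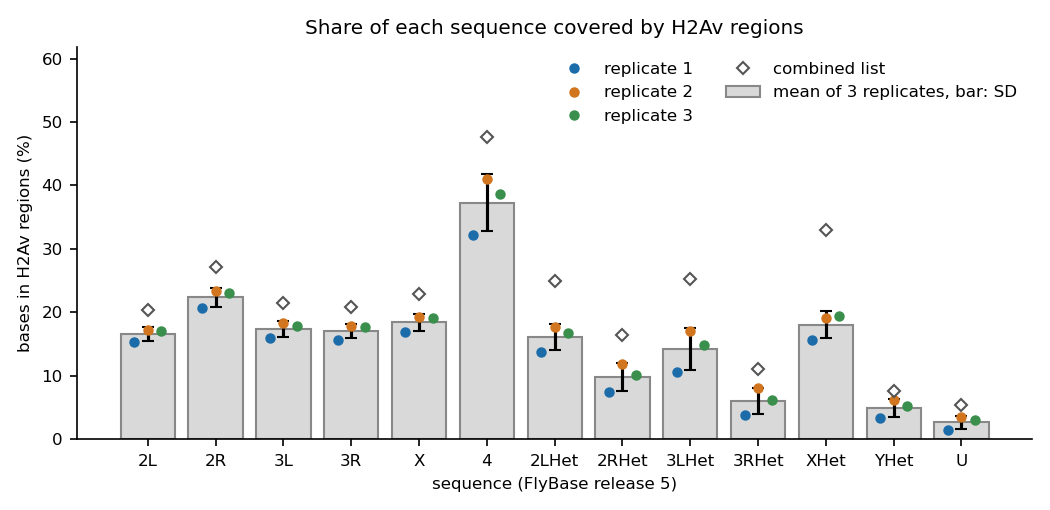
Share of bases inside H2Av regions (%, vertical axis) for the sequences with regions (horizontal axis), with grey bars for the mean of 3 replicates, error bars for the SD, dots for the replicates and diamonds for the combined list. Of the sequences plotted, which leave out Uextra with its 0 regions, chromosome 4 stands highest at 37.3% and U lowest at 2.65%.

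The replicate lists were then compared with each other. The 3 lists placed H2Av at largely the same bases, with a Jaccard index (shared bases over bases in either list) of 0.781 for replicates 1 and 2, 0.795 for 1 and 3 and 0.828 for 2 and 3. Circular shifts of a list along each sequence gave at most 0.156 (one-sided permutation p = 0.001 for each pair, the smallest that 1000 shifts can give). Of the regions of replicate 1, 95.5% shared at least 1 base with replicate 2, against at most 39.0% after shifting, and over all pairs, taken both ways, the share was 78.7 to 95.5%. In all, 19.6 Mb lay in regions of all 3 replicates, which is 71.8% of the 27.3 Mb in regions of any. The overlap was closer on the 5 large arms (mean Jaccard index 0.819 ± 0.022, SD over 3 pairs) and on chromosome 4 (0.771 ± 0.052) than on heterochromatic and unplaced sequence (0.540 ± 0.063). On that sequence replicate 1 held 261 regions, against 475 and 423 in replicates 2 and 3.

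Regions that pairs of replicates shared were ranked much alike by score. The Spearman correlation across shared regions was 0.857 for replicates 1 and 2, 0.866 for 1 and 3 and 0.905 for 2 and 3 (mean 0.876 ± 0.026, SD over 3 pairs), with 4206, 4157 and 4379 shared regions, which are not independent replicates. It was 0.858 ± 0.019 on chromosome 4 and 0.834 ± 0.044 on heterochromatic and unplaced sequence. Among regions near the top of every replicate list were 2R from 3708781 to 3721372, at percentile 99.9, 99.8 and 99.8 of the scores, 3L from 19791744 to 19801905, at 99.7 in each list, and X from 8970873 to 8986012, at 99.9, 99.7 and 99.9. The region on 3R from 18563455 to 18578113 and a further one on X from 15221458 to 15230670 were at percentile 99.6 or above in each replicate. These 5 were chosen after their values were seen, as the combined regions whose lowest percentile over the replicates was highest. They were 9213 to 15140 bp wide in the combined list.

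The last comparison asked what the combined list holds beside the replicates. Nearly all replicate regions were in it, with 99.7 to 99.8% of those of replicates 1 and 2 and 97.6% of those of replicate 3. Of the 5905 combined regions, 3421 (57.9%, 95% exact Clopper-Pearson interval 56.7 to 59.2, counting error only) overlapped a region in all 3 replicates, and these held 84.5% of the combined length. A further 604 (10.2%) overlapped regions in 2 replicates, 814 (13.8%) in 1 and 1066 (18.1%) in none. Regions without a replicate counterpart were short, with a median of 1223 bp against 5495 bp for regions in all 3 replicates, and had a median score of 0.45 against 1.11. Of the unsupported regions, 599 (56.2%) were at most 1300 bp wide, a width below the shortest region of any replicate list. The unsupported regions lay on heterochromatic or unplaced sequence in 22.4% of cases, against 5.26% of the regions in all 3 replicates. Regions in 1 or 2 replicates were much like them, with 22.2% and 21.4% on such sequence and median scores of 0.44 and 0.48. Neither trait is therefore particular to regions in no replicate.

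**Figure D4:**
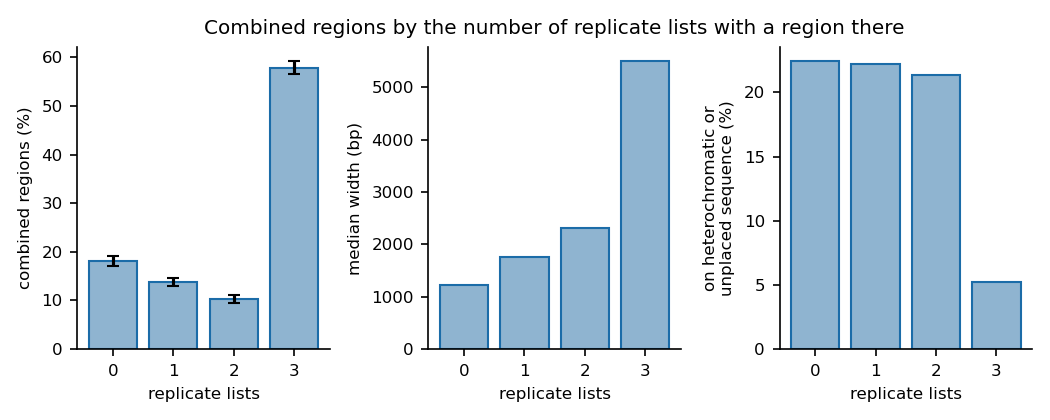
Combined regions by the number of replicate lists with a region there (horizontal axes), as percent of the 5905 regions with 95% exact Clopper-Pearson intervals (left), median width in bp (middle) and percent on heterochromatic or unplaced sequence (right). Regions in all 3 replicates make up 57.9% and have a median width of 5495 bp, against 1223 bp for regions in none.

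The widest combined regions overlapped regions of every replicate, and the highest-scoring were mostly in none. The 5 widest were 3L from 20405528 to 20462990 (57463 bp), 3R from 21038972 to 21086164 (47193 bp), and X from 19531631 to 19570018 (38388 bp), from 2051279 to 2088319 (37041 bp) and from 15342471 to 15379280 (36810 bp). Replicate regions together covered 82.1 to 100.0% of each of them, often as several shorter regions. On 3L the replicate region with the largest overlap was 12528, 15245 and 21771 bp wide, and at the widest on X it was 10953, 11127 and 28530 bp, whereas on 3R replicate 2 had a single region of 46912 bp. Of the 10 highest-scoring combined regions, 7 lay on heterochromatic or unplaced sequence and 8 in no replicate list. The highest score, 3.70, was at U from 351146 to 352382, and the next, 3.56, at 3LHet from 510378 to 511797 and at U from 7152954 to 7153980. Outside the heterochromatic and unplaced scaffolds were 2L from 22795712 to 22797047 and X from 15947828 to 15948913, both with a score of 3.41 and neither in a replicate. So was 2R from 32259 to 34614, with 3.24, which was in replicate 2 alone. The score of this 2R region was shared by 5 combined regions. The regions on 2L and 2R lay in the 2 Mb of their arm next to the centromere, and the region on X did not. Among the 50 highest scores 29 were on heterochromatic or unplaced sequence and 11 in all 3 replicates, whereas of the 50 highest-scoring regions that were in all 3 replicates 2 were on such sequence and 15 on X.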

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

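The alternative without regions whose score another region also has, and all settings for heterochromatic sequence, were chosen after the data were seen. For the 7 results other than the overlap of replicates, 36 of 52 settings kept the direction of a ratio or kept the value within its spread. Settings that leave out 1 replicate could not do otherwise for the ratios, whose sign was the same in all 3 replicates. The same holds for the number of regions and covered length, since dropping 1 of 3 values cannot move a mean by its SD. The count is therefore no measure of stability. The mean Jaccard index was 0.742 to 0.828 and the mean share of shared regions 76.6 to 90.5% over their settings; their permutation p was at its smallest possible value, 0.001, in each, so it says nothing about stability. The log2 ratio of chromosome 4 stayed above 0 and that of heterochromatic sequence below 0, though by less than its SD for regions per Mb without U (-0.28 ± 0.29). The log2 ratio of X to the mean of the 4 autosomal arms was largest, 0.064 ± 0.042, with the highest-scoring 50%. It changed sign to -0.027 without shared scores and to -0.013 for bases in all 3 replicates, so its direction against that mean is not resolved. The cause was not tested. By construction, the number of regions per replicate was lower with the highest-scoring 50% (2363), on the 5 large arms (4246) and without shared scores (4075), and covered length was 16.6 Mb with the highest-scoring 50%. The share of combined regions in all 3 replicates was 64.4% with the highest-scoring 50%, 62.7% on the 5 large arms, 74.2% with equal numbers of regions, 52.2% without shared scores and 47.7% when 50% of both regions had to be shared. It was 58.9 to 65.6% when 1 replicate was left out and the other 2 had to overlap. The rank correlation of scores was 0.787 with the highest-scoring 50%, a narrower range of scores, 0.761 for width, and 0.857 to 0.905 with 1 replicate left out. No paired analysis was possible because the inputs have no list of their own. Unknown depth limits all of these results: whether a region is missing from a list for want of reads was not testable.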

Other observations

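The tests of regions per Mb on chromosome 4, of shared scores and of score percentiles on heterochromatic sequence, and the comparisons of arm ends, of X among the strongest regions, of regions of at least 20 kb and of windows of the length of chromosome 4, were chosen after the result was seen.

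The ends of the autosomal arms next to the centromere had a larger share of bases inside H2Av regions than the mean of the rest of the arm. The end of X had a smaller one. On 2R the 2 Mb from the centromere side had 39.0% ± 3.91 of bases inside regions against 20.6% ± 1.26 on the rest (log2 ratio 0.92 ± 0.061, SD, n = 3). The ratios were 0.69 ± 0.084 on 2L, 0.77 ± 0.17 on 3L and 0.53 ± 0.012 on 3R. On X the same 2 Mb had 10.7% ± 1.06 against 19.2% ± 1.38, a log2 ratio of -0.84 ± 0.042 (SD, n = 3). With the highest-scoring 50% of each list the log2 ratios of end to rest were 0.83 ± 0.060 on 2R, 0.34 ± 0.074 on 3R and 0.26 ± 0.17 on 2L. They were -0.10 ± 0.32 on 3L and -0.86 ± 0.039 on X. On 3L these regions thus showed no excess beyond the spread between replicates, which is too wide to give a direction.

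In each replicate X held a larger share of the strongest regions than of all regions, but by little in replicates 2 and 3. Of the highest-scoring 5% of regions on the 5 large arms, 28.7%, 21.2% and 22.2% lay on X in the 3 replicates, against 19.1%, 19.3% and 18.9% of all regions (log2 ratio 0.32 ± 0.24, SD, n = 3). These are 58 of 202, 47 of 222 and 47 of 212 regions, and their counting error was not computed. Replicate 1 has the largest excess, and without it the values are those of replicates 2 and 3, log2 ratios of 0.13 and 0.23. Regions of at least 20 kb were 2.79% ± 0.398 of those on chromosome 4, 1.56% ± 0.498 on X and 1.14% ± 0.328 on the autosomal arms (SD, n = 3). The share on chromosome 4 rests on 2, 3 and 3 regions, and in replicate 2 X and the autosomal arms had nearly the same share, 1.40% and 1.37%.

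Chromosome 4 was covered 2.03-fold above the autosomal arms. A few long regions would leave its number of regions per Mb at or below that of the arms, and the log2 ratio of that number was 0.97 ± 0.071 (SD, n = 3), which argues against them as the whole source. Weak regions alone are argued against by the highest-scoring 50% of each list, where the log2 ratio of covered share was 0.58 ± 0.35, although it was down from 1.02. In replicates 1, 2 and 3 it went from 0.94, 1.10 and 1.03 to 0.24, 0.94 and 0.57. Weaker regions may thus make up part of the excess, and much of it in replicate 1. Of 86 windows of the same length along the 5 large arms, 1, 2 and 1 reached its share in the 3 replicates, and the highest in each was the centromere-side end of 2R, from 1 to 1351857. No biological explanation was tested, and sequence that reads cannot be aligned to stays open.

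The highest scores of the combined list were mostly in short regions of heterochromatic or unplaced sequence. A candidate explanation is coarse scores of few reads, since a ratio of few reads takes few values and would make scores coincide. Of the 50 highest-scoring combined regions, 60.0% (95% exact interval 45.2 to 73.6) had exactly the score of another region, against 14.2% of the others, and their median width was 1171 bp against 3401 bp. Of the 50 highest-scoring regions in all 3 replicates, 0 shared a score, but these were wide, with a median of 9342 bp. Among the 50 highest-scoring regions of each replicate's own list, 0, 2 and 2 shared a score, so few top scores coincided there. Copies of a repeat that are absent from the assembly were not tested and stay open, and no biological explanation was tested.

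Replicate 1 had the fewest regions on heterochromatic and unplaced sequence, 5.93% of its list against 9.47% and 8.88% in replicates 2 and 3. With lists cut by score to equal length the shares were 5.93%, 9.04% and 8.59%. Replicate 1 was still lower by 2.66 percentage points than the nearer of the others. This argues against the number of regions alone as the cause. The caller's own criterion is unknown and may differ from the score, so a stricter call in replicate 1 stays open. Weak regions near the threshold may account for part of the gap, since such regions of replicates 2 and 3 that replicate 1 lacks had a median score percentile that differed by -10.0 from that of the regions it has. The difference was -9.28 between replicates 2 and 3, so losing weak regions is not particular to replicate 1. The experiment numbers that set replicate 1 apart, and an unknown difference in depth, stay open with 1 list on that side, and no biological explanation was tested.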
